A study of Arabidopsis thaliana with 9 samples.

How the data were processed

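Seedlings were grown for 14 days on solid medium, and liquid medium with 25 or no µg/ml doxycycline was added for 12 h, per the labels' protocols. RNA was enriched for polyA transcripts and sequenced as Ion Torrent libraries, per the labels' protocols. The series' design text states biological replicates, 3 per condition. The deposited values are FPKM, fragments scaled by transcript length and by the library's mapped total, in 2 tables. The submitters' processing notes name FastQC 0.10.1, Cufflinks 2.2.1 and the build TAIR10, with no role or order; the aligner is not given in the sources used here. FPKM divides by transcript length, so a few reads on a transcript of under 300 nt give a high value, and Cufflinks can list 0 where an estimate failed, so such genes are described as listed at 0 and given per library without a fold change. Because FPKM is relative to each library's total, a change in abundant organelle transcripts moves all other genes.

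The 12 sample columns of the tables, all used, were matched to samples by name. The wild-type columns of the tables held the same libraries up to a factor per library of 0.94057, 0.94058 and 0.94147, so each comparison with wild type was fitted within its own table. For doxycycline against mrpl1-1 the mutant columns were divided by the median factor, 0.94058. Depth was estimated from low values, which fall on whole multiples of the value of 1 read: between 56.3% and 63.6% of ratios between libraries were ratios of whole numbers up to 6 within a tolerance of 0.005, against 5.77% to 6.75% at wrong steps. This gave between 3.41 and 8.95 M reads on genes per library. These are not exact read counts, so no count test was run.

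Log2(FPKM + 1) values of genes with a mean of at least 1 FPKM were tested with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. Fold changes from the fit are on that scale and understate the change of genes with low FPKM; folds of mean FPKM are given where named as such. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 20 lists, and again with an estimated correlation and with fry. With an estimated correlation none of these 20 lists was called at an adjusted p under 0.05 in any comparison; the lowest values were 0.222 with doxycycline, 0.551 for mrpl1-1 and 0.183 for the difference. The 20 lists (18 of named loci, holding 355 distinct loci, and the mitochondrion- and plastid-encoded loci by prefix), the tests, the groups and the rule for named genes were fixed before the data were examined. The rule took MRPL1 and AOX1A, the 6 largest rises and 6 largest falls among called genes with at least 5 FPKM in the higher group and no overlap of replicates, and up to 2 called members per list, or else the member with the smallest p. For the comparison of responses it took the genes called in both and the 4 largest differences in each direction. Other genes named in the text were chosen after their values were seen.

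Simulated data were made from the means and spreads of each comparison, with 200 genes above a minimum mean level changed 2- or 4-fold. The fit recovered 98.4% of 4-fold and 72.0% of 2-fold changes over the 19073 genes of doxycycline against control. It recovered 97.2% and 38.8% over the 18994 genes of mrpl1-1 against wild type, and 98.0% and 59.8% over the 19105 genes of the difference. So many planted changes loosen the adjusted cutoff, so recovery in data with fewer changes, or of genes with low FPKM, may be lower. Simulated unchanged groups for the shared controls used 100 draws with the spread of the fit of 9 libraries.

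Gene symbols, coordinates and lengths came from the RefSeq annotation of TAIR10.1, in which 32810 loci had a match and 747 did not. Coordinates are of that build and were not taken from the deposited tables. Organelle loci are given by their identifiers, and the names AT12CYS-2, HSP23.5 and MRPL1, which the annotation gives as locus names, came from the lists. Strand use in the authors' quantification is not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies such as the neighbouring GSTU24 and GSTU25.

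Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-ratio rescaling, quantile normalization, limma without trend, robust moderation, array weights, the replicate number as a block, a 2-fold minimum, organelle-encoded genes left out, and each library left out. Added after seeing the data were fits on genes above 0 in every library, with and without array weights, fits without both libraries that stood apart, fits on protein-coding genes of at least 300 nt, 3 further lists and 12 families by product name, and the fixed lists in doxycycline against mrpl1-1.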

Results

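Transcript levels were measured by polyA RNA sequencing on an Ion Torrent Proton instrument in 14-day-old seedlings of Arabidopsis thaliana, accession Col-0. The 9 libraries fell into 3 groups of 3 biological replicates: untreated wild type, wild type given 25 µg/ml doxycycline for 12 h, and untreated seedlings of the mutant mrpl1-1 kept in the same liquid medium without the drug. Doxycycline is a tetracycline that inhibits translation in mitochondria, and also in plastids. By its title the series addresses the response to impaired mitochondrial translation. The values were FPKM in 2 tables, and the wild-type libraries served as controls in both. Depth, recovered from the smallest steps between FPKM values, was 8.95, 6.24 and 3.41 M reads on genes in wild-type replicates 1 to 3. It was 7.71, 7.21 and 5.79 M in the doxycycline libraries and 3.59, 6.23 and 8.24 M in those labelled mrpl1-1. At these depths 1 read in a transcript of 1 kb corresponded to between 0.119 and 0.320 FPKM in the table with doxycycline. Wild-type replicate 3 and mrpl1-1 replicate 2 stood apart from the other libraries: the second principal component (20.1% of the variance) was led by the former and the first (23.9%) by the latter.

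The gene named in the mutant's label was examined first. MRPL1 (AT2G42710) encodes a ribosomal protein of the L1p/L10e family and lies on the plus strand of chromosome 2 at 17782308 to 17785090 in TAIR10.1, with 10 exons. The labels do not give the locus, which was taken from background knowledge. Its FPKM was 19.6, 12.0 and 18.6 in the 3 libraries labelled mrpl1-1 and 19.4, 17.9 and 25.1 in wild type of the same table. The log2 fold change of -0.31 (SE 0.23) did not pass the test (limma, adjusted p = 0.931). In the table with doxycycline the level was 22.4 ± 0.334 FPKM (SD, n = 3) with the drug and 22.1 ± 3.99 (SD, n = 3) without it (limma, adjusted p = 0.964). The level of this transcript therefore gave no check of the mutant's label, and the directions below refer to the libraries labelled mrpl1-1.

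The first comparison asked which transcripts differed after 12 h of doxycycline. Of 23 measured genes of the mitochondrial retrograde response, induced in the nucleus when mitochondria are disturbed, 5 rose with the drug, as did 4 of 25 genes of detoxification, while none of 11 root tissue markers passed over all genes. Camera called the retrograde and detoxification lists as higher and the root markers as lower, but with an estimated correlation none was called (adjusted p = 0.222, 0.242 and 0.223). Fry called the retrograde list (adjusted p = 0.0244) and the root markers (0.0403), but not the detoxification list (0.119). AT12CYS-2 (AT5G09570, chromosome 5, 2970498 to 2972222), a small Cox19-like protein with CHCH motifs, rose from 1.54 ± 0.368 to 19.4 ± 7.61 FPKM (SD, n = 3), which is 12.7-fold in the means. GSTU25 (AT1G17180, chromosome 1, 5872024 to 5873124), a tau-class glutathione transferase, rose from 9.54 ± 3.39 to 76.8 ± 21.0 FPKM (SD, n = 3). The calls of AT12CYS-2 and GSTU25 were lost without doxycycline replicate 1 (limma, adjusted p = 0.126 and 0.0894), and also without wild-type replicate 1 or 2 or doxycycline replicate 2. RHS13 (AT4G02270, root hair specific 13, chromosome 4, 992111 to 993039) fell from 61.5 ± 4.48 to 18.7 ± 2.05 FPKM (SD, n = 3). In all, 35 of 19073 genes tested differed, 22 higher and 13 lower (limma, adjusted p under 0.05), and 1619 had an unadjusted p under 0.05 where 954 were expected by chance. Replicates of the 2 groups did not overlap for 16.0% of the genes, against 10% by chance. The doxycycline libraries correlated with transcript length when set against the mean of the other groups' libraries (Spearman rho 0.204, 0.254 and 0.297). Wild-type libraries measured likewise lay between -0.0401 and 0.0319. How far this length trend shaped the doxycycline results was not tested.

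The mitochondrial retrograde list, fixed before the data were examined, had 23 measured members, of which 5 rose and none fell, and 20 rose when adjusted over the list alone. The median log2 fold change was 1.35 (camera, adjusted p = 3.5e-29; adjusted p = 0.222 with an estimated correlation). Besides AT12CYS-2, the members that rose included AT2G04050, a MATE efflux protein (log2 fold change 3.26, SE 0.29, limma adjusted p = 0.0128), and ABCB4 (AT2G47000), an ABC transporter of auxin (1.52, SE 0.13, adjusted p = 0.0128). NDB2, an external NAD(P)H dehydrogenase of mitochondria, rose from 8.97 ± 0.273 to 19.7 ± 1.00 FPKM (SD, n = 3; adjusted p = 0.0190). AOX1A (AT3G22370), the alternative oxidase often used as the marker of this response, measured 79.3, 59.1 and 71.4 FPKM with doxycycline and 24.0, 22.1 and 43.5 without it. Each library with the drug lay above the controls, but the log2 difference of 1.26 (SE 0.25) did not pass the test over all genes (limma, adjusted p = 0.188).

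Of 25 measured glutathione transferases and detoxification genes, 4 rose and none fell. Adjusted over the list alone, 11 rose and 1 fell, and the median was 0.55 (camera, adjusted p = 1.1e-10; adjusted p = 0.242 with an estimated correlation). UGT73B4, a glycosyltransferase, rose 4.25-fold in mean FPKM (limma, adjusted p = 0.00794), GSTU24 rose 4.19-fold (adjusted p = 0.0128) and GSTU9 rose 4.32-fold (adjusted p = 0.0412). Among 24 mitochondrial chaperones and proteases no gene passed the test over all genes, while 6 rose when adjusted over the list alone. The list was higher by a median of 0.25 (camera, adjusted p = 1.6e-06; adjusted p = 0.242 with an estimated correlation). HSP23.5, a small heat shock protein of mitochondria, was at 31.4 ± 9.08 FPKM against 11.4 ± 3.70 (SD, n = 3; limma, adjusted p = 0.151).

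Root tissue markers were lower with doxycycline. None of 11 measured members passed the test over all genes (limma; 6 were lower and 1 higher at an unadjusted p under 0.05), 6 fell when adjusted over the list alone, and the median was -0.30 (camera, adjusted p = 9.7e-06; adjusted p = 0.223 with an estimated correlation). LRX1, an extensin of root hair walls, was at 4.18 ± 0.914 FPKM against 11.1 ± 2.03 (SD, n = 3; limma, adjusted p = 0.0797). Genes of aliphatic glucosinolate synthesis were lower by a median of -0.43, with 5 of 13 lower when adjusted over the list alone (camera, adjusted p = 8.6e-06; adjusted p = 0.317 with an estimated correlation). BCAT4, the aminotransferase of the first step of methionine chain elongation, was at 90.0 ± 14.5 FPKM against 144.7 ± 16.3 (SD, n = 3; limma, adjusted p = 0.228). Smaller shifts were called for ethylene genes (median 0.22, adjusted p = 0.0131), jasmonate genes (median -0.28, adjusted p = 0.0159) and nuclear photosynthesis genes (median -0.12, adjusted p = 0.0171). With an estimated correlation these had adjusted p = 0.450, adjusted p = 0.770 and adjusted p = 0.450. No member of these 3 lists passed over all genes or adjusted over the list alone, and each call was lost on leaving out doxycycline replicate 1. The ethylene and photosynthesis calls were also lost without wild-type replicate 2, the jasmonate call without wild-type replicate 1 or 3, and the photosynthesis call with quantile normalization. JAZ7, the jasmonate gene with the smallest p, lay on the higher side at 1.29 (SE 0.33; limma, adjusted p = 0.340).

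The remaining 12 lists were not called in this comparison. Their medians were 0.02 for cytosolic heat shock genes (camera, adjusted p = 0.652), -0.04 for auxin response (0.470), -0.02 for salicylate and pathogen defence (0.658) and -0.03 for abscisic acid response (0.658). They were -0.09 for the nuclear-encoded respiratory chain (0.470), 0.01 for mitochondrial ribosomal proteins (0.658), 0.10 for plastid chaperones (0.0714) and -0.01 for antioxidant enzymes (0.658). They were 0.12 for the circadian clock (0.470), -0.06 for the cell cycle (0.642), -0.03 for mitochondrion-encoded genes (0.658) and -0.05 for plastid-encoded genes (0.470). The mean of the heat shock list was -0.05 although its median and test were on the higher side, and the mean of the antioxidant list was 0.07 although its median lay below 0. For plastid-encoded genes camera pointed lower and fry higher, and ATCG00230 was the member that passed over all genes. At an unadjusted p under 0.05 (limma) 8 of 97 were higher and 15 lower, where 1619 of all 19073 genes passed in either direction. Fry for a change in either direction gave this list adjusted p = 1.9e-05, so its small median does not show that its members were unchanged. How far ATCG00230, listed at 0 in every control, carried this value was not tested. The other members named from these lists lay between -0.87 (SAUR24) and 1.06 (ZAT12), and the smallest adjusted p among them was 0.180 (DREB2A, limma).

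Other genes with large changes included AT2G38823, an uncharacterised protein that rose from 0.360 ± 0.325 to 10.7 ± 3.64 FPKM (SD, n = 3; limma, adjusted p = 0.0146). AGP22, an arabinogalactan protein, fell from 17.3 ± 5.77 to 2.22 ± 0.961 FPKM (SD, n = 3; adjusted p = 0.0393). The lipid-transfer-like genes AT4G22666 (log2 fold change -1.93, adjusted p = 0.0224) and AT5G46900 (-1.70, adjusted p = 0.0481) and the pectin methylesterase inhibitor gene AT5G62340 (-1.85, adjusted p = 0.0206) also fell. For 4 called genes every library of 1 group was listed at 0. ATCG00230 was listed at 0 in the 3 controls and at 124, 257 and 161 FPKM with doxycycline, and AT3G54530 at 0 in the controls and at 7.76, 11.5 and 7.3 FPKM. AT2G03130 was listed at 0 in the controls and at 4.54, 5.66 and 3.56 FPKM, and was named after its values were seen. Neither AT3G54530 nor AT2G03130 was particular to doxycycline. In the libraries labelled mrpl1-1 AT3G54530 was listed at 0.58, 1.19 and 0.67 FPKM and AT2G03130 at 3.82, 3.91 and 1.56 FPKM. AT1G74456, a small nucleolar RNA of 82 nt, was listed at 0 with doxycycline and at 74.3, 212 and 197 FPKM in the controls. The count of 35 rested on the libraries used: it was 23, 13 and 91 without wild-type replicates 1, 2 and 3, and 9, 15 and 10 without doxycycline replicates 1, 2 and 3. The retrograde, detoxification, chaperone, glucosinolate and root lists kept their calls in each of these 6 fits. Among single genes measured in every library, RHS13 kept its call under all alternatives run for it. ATCG00230, AT3G54530 and AT1G74456, each listed at 0 in 1 group, also kept theirs. For a short transcript such as AT1G74456 (82 nt) a few reads give a high FPKM, so a kept call there does not show a robust change. Without doxycycline replicate 1 the calls of AT12CYS-2, GSTU25, AT2G04050, ABCB4, UGT73B4, GSTU24, AT2G38823, AGP22, AT4G22666, AT5G62340 and AT5G46900 were lost (limma, adjusted p from 0.0709 for UGT73B4 to 0.256 for AT5G46900). AT5G46900 lost its call without any 1 of the 6 libraries, and AGP22 without any but wild-type replicate 3 (adjusted p up to 0.137). Leaving out wild-type replicate 1 ended, of the others, the calls of AT12CYS-2 (0.0640) and GSTU25 (0.0528). Leaving out wild-type replicate 2 ended those of AT12CYS-2, GSTU25, ABCB4, AT2G38823, AT4G22666 and AT5G62340 (0.0716 to 0.104). Leaving out doxycycline replicate 2 ended those of AT12CYS-2, GSTU25, AT2G04050, GSTU24, AT4G22666 and AT5G62340 (0.0690 to 0.120), and doxycycline replicate 3 those of AT2G04050, ABCB4, UGT73B4, GSTU24, AT2G38823, AT4G22666 and AT5G62340 (0.0630 to 0.128).

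**Figure D1:**
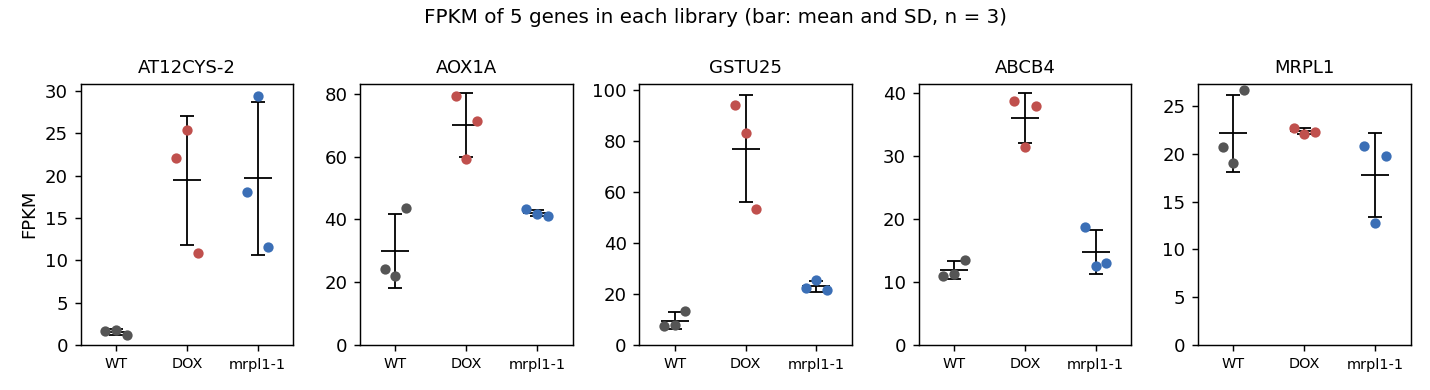
FPKM (vertical axes, from 0) of AT12CYS-2, AOX1A, GSTU25, ABCB4 and MRPL1 in each library of the 3 groups; dots are libraries, and bars give the mean and SD (n = 3), with the mrpl1-1 values set on the scale of the other table. AT12CYS-2 was higher in both the doxycycline and the mrpl1-1 libraries, whereas the MRPL1 values of either group overlapped with those of wild type.

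The second comparison asked which transcripts differed between the libraries labelled mrpl1-1 and wild type. AT12CYS-2 was 12.8-fold higher in mean FPKM, at 18.5 ± 8.50 against 1.45 ± 0.346 (SD, n = 3; limma, adjusted p = 0.0289). SEN1 (AT4G35770, chromosome 4, 16944878 to 16946266), a senescence-associated and dark-induced gene, was 5.87-fold higher at 16.1 ± 1.59 against 2.73 ± 0.957 FPKM (SD, n = 3; adjusted p = 0.0289). The call of AT12CYS-2 was lost in 7 of 12 alternatives (limma, adjusted p from 0.0169 to 0.169 over all 12), among them those without wild-type replicate 1, 2 or 3 or mrpl1-1 replicate 1 or 2. That of SEN1 was lost in 6 of 12 (0.0216 to 0.245), among them those without wild-type replicate 2 or mrpl1-1 replicate 1, 2 or 3. Altogether 7 of 18994 genes differed, 5 higher and 2 lower, and 848 had an unadjusted p under 0.05 where 950 were expected by chance. With organelle-encoded genes left out the split was 5 higher and 1 lower. Replicates of the groups did not overlap for 10.1% of genes, against 10% by chance.

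The other 5 called genes were listed at 0 in every library of 1 group. AT2G44130, a kelch repeat protein, was listed at 0 in wild type and at 9.21, 19.1 and 8.85 FPKM in the libraries labelled mrpl1-1. AT5G40180, an acyl-esterase family gene, was listed at 0 and at 9.17, 12.5 and 7.50 FPKM, and the pseudogene AT2G35743 (180 nt) at 0 and at 12.0, 8.19 and 4.91 FPKM. The call of AT2G35743 was lost in 7 of 12 alternatives (limma, adjusted p up to 0.263), among them those without wild-type replicate 1, 2 or 3 or mrpl1-1 replicate 1 or 2, and that of AT2G44130 with a pseudocount of 5 (0.0751). In the other direction, the plastid locus ATCG00410 was listed at 210, 300 and 278 FPKM in wild type and at 0 in the libraries labelled mrpl1-1. The small nucleolar RNA AT1G20015 (89 nt) was listed at 158, 225 and 279 FPKM in wild type and at 0 in the mutant libraries. In doxycycline replicates 1 to 3 ATCG00410 was listed at 259, 0 and 0 FPKM and AT1G20015 at 0, 67.4 and 0 FPKM. Listing at 0 was thus not particular to the libraries labelled mrpl1-1. For a transcript of 89 nt a few reads give a high FPKM, so the size of that fall does not show a large change.

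Of 21 measured retrograde response genes only AT12CYS-2 rose, over all genes and adjusted over the list alone. The list's median was 0.51, with 19 members on the higher side (camera, adjusted p = 2.9e-09; adjusted p = 0.551 with an estimated correlation). AOX1A was at 40.7, 39.2 and 38.7 FPKM against 22.6, 20.7 and 40.9 in wild type (limma, adjusted p = 0.931). Among 17 salicylate and pathogen defence genes none passed over all genes and 3 were higher when adjusted over the list alone, with a median of 0.43 (camera, adjusted p = 0.000132; adjusted p = 0.551 with an estimated correlation). WRKY70, a transcription factor of this pathway, was at 115 ± 8.58 FPKM against 46.2 ± 6.19 (SD, n = 3; limma, adjusted p = 0.0948).

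Camera also called mitochondrion-encoded genes (median 0.45, adjusted p = 0.000379), plastid-encoded genes (0.31, adjusted p = 0.00858), nuclear photosynthesis genes (0.24, adjusted p = 0.00295), abscisic acid genes (0.27, adjusted p = 0.0269) and mitochondrial chaperones (0.14, adjusted p = 0.0134) as higher. Jasmonate genes (median -0.27, adjusted p = 0.00264) and cytosolic heat shock genes (-0.18, adjusted p = 0.0142) were called as lower. With an estimated correlation each of these 7 lists had adjusted p = 0.551. The organelle lists rest on the 33 of 146 mitochondrion-encoded and 94 of 133 plastid-encoded loci measured, in libraries enriched for polyA transcripts. The calls of the mitochondrion-encoded, plastid-encoded, photosynthesis, abscisic acid and mitochondrial chaperone lists were lost without mrpl1-1 replicate 2, 1 of the libraries that stood apart, and that of the heat shock list without wild-type replicate 3. Leaving out wild-type replicate 1 ended the calls of the plastid-encoded, photosynthesis, jasmonate, abscisic acid and chaperone lists. The abscisic acid and chaperone calls were lost without wild-type replicate 2 as well, and the abscisic acid call without mrpl1-1 replicate 1. The photosynthesis call was also lost with quantile normalization (adjusted p = 0.286), and the heat shock call with a filter of 5 FPKM (0.296) and on genes above 0 in every library (0.0800). With both libraries that stood apart left out, the heat shock, jasmonate, photosynthesis and mitochondrion-encoded calls were lost. RD20 of the abscisic acid list (-0.82; limma, adjusted p = 0.931) and ATMG01130 of the mitochondrion-encoded list (-2.19; adjusted p = 0.513) lay against the direction of their lists.

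The 11 lists not called had medians of 0.06 for ethylene (camera, adjusted p = 0.157), -0.13 for auxin (0.340), 0.05 for the nuclear-encoded respiratory chain (0.157), 0.00466 for mitochondrial ribosomal proteins (0.978) and -0.16 for plastid chaperones (0.112). They were 0.04 for detoxification genes (0.228), 0.34 for antioxidant enzymes (0.0558), 0.07 for glucosinolate synthesis (0.378), 0.12 for the clock (0.376), 0.00816 for the cell cycle (0.372) and 0.11 for root markers (0.165). ERF6, an ethylene response factor, was at 13.7 ± 2.62 FPKM against 4.01 ± 2.02, and GSTU25 at 21.6 ± 1.93 against 8.97 ± 3.198 (SD, n = 3); neither passed over all genes (limma, adjusted p = 0.388 for both). The count of 7 became 11 without mrpl1-1 replicate 3, and it was 7 without both libraries that stood apart, with 2 higher, 5 lower and 3 genes in common with the full set.

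**Figure D2:**
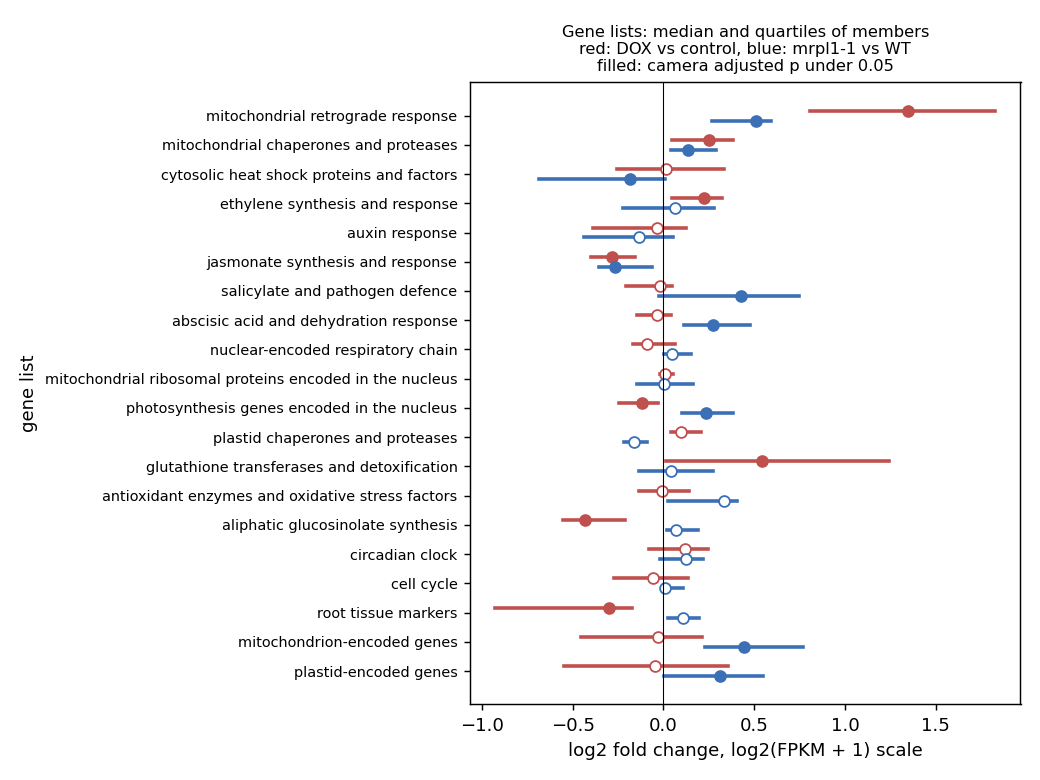
Median (dot) and quartiles (line) of the log2 fold changes of each gene list's members, in doxycycline against control (red) and in mrpl1-1 against wild type (blue), on the log2(FPKM + 1) scale; filled dots mark lists with a camera adjusted p under 0.05 at the preset correlation. The retrograde response list lay at 1.35 with doxycycline and at 0.51 in the libraries labelled mrpl1-1, and none of the filled lists was called with an estimated correlation.

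The 2 responses were set side by side over the 18759 genes tested in both tables. AT12CYS-2 was the only gene that passed in both, and its call was lost in 4 of 12 alternatives with doxycycline and in 7 of 12 with mrpl1-1. Log2 fold changes correlated across genes with r = 0.41, while simulated unchanged groups against the same controls gave 0.50 on average (0.45 to 0.55 in 100 draws). The covariance was 0.0524 against a simulated 0.0388, but the variance of the controls themselves, divided among 3 libraries, came to 0.0623, so the sign of the excess depended on the estimate of the control spread. Over the 18298 genes above 0 in every library the covariance was 0.0270 against 0.0383 from the controls. At an unadjusted p under 0.05, 82 genes were higher in both and 70 lower in both. Simulated unchanged groups shared 88.9 and 98.5, and independent lists of these sizes would share 18.6 and 14.7. In opposite directions 30 genes passed, against 2.78 in the simulations. With 3 controls these could not be split between the comparisons. The overlap in the same direction at an unadjusted p under 0.05 did not exceed that of the simulated unchanged groups, so sharing the controls could give counts of this size. This does not cover AT12CYS-2: genes called higher in both averaged 0.01 in the simulations (0 to 1 in 100 draws), against 1 observed. The simulations gave each gene the same spread in all groups, whereas doxycycline libraries varied less than those labelled mrpl1-1, so their counts are a rough guide. Genes are not independent replicates.

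The difference between the responses was tested directly as doxycycline against mrpl1-1, with the tables set on 1 scale by the wild-type libraries. In the doxycycline libraries 3 of 25 detoxification genes and 4 of 23 retrograde response genes were higher, and 4 of 12 root markers and 1 of 17 defence genes were lower. Camera called the 4 lists in these directions, but with an estimated correlation none was called (adjusted p = 0.212, 0.183, 0.183 and 0.267). Fry called the detoxification (adjusted p = 0.0341), retrograde (0.0169) and root marker lists (0.0169), but not the defence list (0.0576). GSTU24 was at 84.7 ± 10.4 FPKM with doxycycline and 16.2 ± 0.730 in the libraries labelled mrpl1-1 (SD, n = 3; limma, adjusted p = 0.000721). GSTF14 (AT1G49860), a phi-class glutathione transferase, was at 15.75 ± 2.71 against 92.3 ± 6.90 FPKM (SD, n = 3; adjusted p = 0.00439), with 34.8 ± 13.3 in wild type. RHS13 was at 18.7 ± 2.05 against 105 ± 48.1 FPKM (SD, n = 3; adjusted p = 0.00974, or 0.0510 without doxycycline replicate 1), and WRKY70 at 54.9 ± 1.42 against 122 ± 9.12 (SD, n = 3; adjusted p = 0.00979). In all 70 of 19105 genes differed, 19 higher and 51 lower with doxycycline, and 2145 had an unadjusted p under 0.05 where 955 were expected by chance. Without organelle-encoded genes the split was 40 higher and 49 lower. The count was 150 without wild-type replicate 3. It was 17, 41 and 25 without doxycycline replicates 1, 2 and 3, and 33, 30 and 197 without mrpl1-1 replicates 1, 2 and 3.

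Testing the lists in this contrast was chosen after seeing the data. The retrograde list was higher with doxycycline by a median of 0.71, with 4 of 23 members higher over all genes and 15 adjusted over the list alone (camera, adjusted p = 5.3e-14; adjusted p = 0.183 with an estimated correlation). Detoxification genes were higher by a median of 0.55, with 3 of 25 members higher (camera, adjusted p = 2.6e-08; adjusted p = 0.212 with an estimated correlation). Root markers were lower by a median of -0.54, with 4 of 12 members lower over all genes, LRX1, COBL9, EXP7 and GLL22 (camera, adjusted p = 6.1e-06; adjusted p = 0.183 with an estimated correlation). Salicylate and defence genes were lower by a median of -0.57, with WRKY70 the member that passed over all genes (camera, adjusted p = 3.4e-05; adjusted p = 0.267 with an estimated correlation). Camera called 8 further lists: cytosolic heat shock (median 0.42) and plastid chaperones (0.19) as higher with doxycycline, and abscisic acid (-0.30), respiratory chain (-0.10, but on the higher side with quantile normalization, adjusted p = 0.743), photosynthesis (-0.34), glucosinolate (-0.44), mitochondrion-encoded (-0.56) and plastid-encoded genes (-0.39) as lower. With an estimated correlation none of the 8 was called; the smallest value was the glucosinolate list's adjusted p = 0.203. Of these 8, fry called the glucosinolate list alone (adjusted p = 0.0341). Without mrpl1-1 replicate 2 the calls of the respiratory chain (camera, adjusted p = 0.841), mitochondrion-encoded (0.167) and plastid-encoded lists (0.195) were lost. The respiratory chain call was also lost without doxycycline replicate 2 (0.0845) or 3 (0.0566), the abscisic acid call without mrpl1-1 replicate 1 (0.121), and the photosynthesis call with quantile normalization (0.240).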

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

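Tests of transcript length in wild-type replicate 3 and of depth in each of the libraries that stood apart were chosen after their results were seen, and the test of short transcripts was extended to a further gene afterwards; the patterns had been seen before any of the tests was chosen. The effects of doxycycline and of the mutant differed by a test of the difference itself, and the 4 genes with the largest fitted difference in each direction are given here. On the log2 scale doxycycline minus mrpl1-1 was 2.42 for AT2G04050, 2.39 for AT3G54530, -2.49 for GSTF14 and -2.33 for RHS13. The other 4 were listed at 0 in every library of 1 group. ATCG00230 was listed at 124, 257 and 161 FPKM with doxycycline and at 0 in the libraries labelled mrpl1-1 (limma, adjusted p = 4.2e-07). AT2G22820 was listed at 24.9, 6.37 and 15.01 FPKM with doxycycline, at 0 in the libraries labelled mrpl1-1 and at 0, 3.69 and 0 in wild type (adjusted p = 0.0284). AT2G44130 was listed at 0 with doxycycline and at 9.79, 20.3 and 9.41 FPKM in the libraries labelled mrpl1-1 on the same scale (adjusted p = 0.000721), and AT2G35743 at 0 and at 12.8, 8.71 and 5.22 FPKM (adjusted p = 0.00282). Without doxycycline replicate 1 the calls of RHS13 (limma, adjusted p = 0.0510), AT2G22820 (0.135) and AT2G04050 (0.142) were lost. The latter pair also lost theirs without doxycycline replicate 3 (0.131 and 0.0997), mrpl1-1 replicate 1 (0.105 and 0.0530) or mrpl1-1 replicate 2 (0.121 and 0.0732), and AT2G04050 without doxycycline replicate 2 (0.112). With a pseudocount of 0.1 AT2G22820 and AT2G04050 lost their calls too (limma, adjusted p = 0.0525 and 0.0787), as did AT2G22820 with the replicate block (0.0654).

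Chance assignment of libraries to groups cannot be tested to 0.05 here, since 6 libraries make 10 splits into 3 and 3 and the share is never under 0.1. In each comparison only the real split, 1 of 10, gave as many calls. The real and the highest other counts were 35 and 5 for doxycycline, 7 and 3 for mrpl1-1 and 70 and 2 for the difference.

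Root markers had a median below 0 with doxycycline, with none of 11 members called over all genes (camera, adjusted p = 9.7e-06 for the list; adjusted p = 0.223 with an estimated correlation). The medians over fits that each left out 1 control library reached -0.26 at most, below the bound of -0.1 set beforehand, which argues against a fall carried by a single control. A lower share of root tissue stays open: root markers outside root hairs had a median of -0.18, between the bounds set for either outcome, while root hair genes, a list made after the fall had been seen and sharing LRX1, COBL9 and EXP7 with the root markers, had a median of -1.04. Of 19 measured members outside root hairs 13 were lower and 6 higher (camera, adjusted p = 0.0470, or 0.441 with an estimated correlation). A change within root hairs may account for part of the fall.

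Of the 10 genes called in any of the 3 comparisons with every library of 1 compared group at 0, short transcripts could be the source, because few reads give them high FPKM. Of the 8 with an annotated length, 37.5% were shorter than 300 nt, against 0.794% of the genes tested with doxycycline. This lay between the bounds set for either outcome and leaves the set as a whole open. The plastid loci ATCG00230 and ATCG00410 had no annotated length and were not counted, so the share could change with their lengths. For AT2G35743 (180 nt) the libraries labelled mrpl1-1 held 12.0, 8.19 and 4.91 FPKM. These values ran parallel to that of 1 read in a 1 kb transcript (0.292, 0.199 and 0.118 FPKM), as equal read numbers would give. AT1G74456 was listed at 181 FPKM in mrpl1-1 replicate 1 and at 0 in replicates 2 and 3, so such a gene can be listed at 0 within a group as well. No biological explanation was tested.

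Wild-type replicate 3 and mrpl1-1 replicate 2 stood apart from the rest. Among genes with at least 50 FPKM, where sampling noise is small, mrpl1-1 replicate 2 deviated 1.62 times and wild-type replicate 3 1.69 times the median of the other 7 libraries, of which mrpl1-1 replicate 3 reached 1.51 and mrpl1-1 replicate 1 1.13 (SD of the 7, 0.334). Lower depth is argued against for both: mrpl1-1 replicate 2 (6.23 M reads) held 1.74 times the reads of mrpl1-1 replicate 1 (3.59 M), the library nearest in depth to wild-type replicate 3 (3.41 M), and each deviated more than that library by more than the SD. The deviation of mrpl1-1 replicate 2 from its sister libraries correlated with transcript length across genes (Spearman rho -0.318). Replicates 1 and 3 lay at 0.251 and 0.165, but deviations within a group balance out, so these give no separate support. Against the mean of the other groups' 6 libraries rho was -0.325 for replicate 2, -0.0104 for replicate 1 and -0.0972 for replicate 3. This goes with a length bias of replicate 2, although doxycycline libraries measured likewise lay at 0.204 to 0.297. For wild-type replicate 3 rho was -0.0239, which argues against such a bias there, and what sets that library apart stays open.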

How the results depend on the processing

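Fits on genes above 0 in every library, on protein-coding genes and without both libraries that stood apart, and all fits of the lists in doxycycline against mrpl1-1, were chosen after seeing the data. Doxycycline against control called 35 genes; other pseudocounts, a filter of 5 FPKM, rescaling, quantile normalization, robust moderation, a 2-fold minimum and organelle genes left out gave within 1.5 times that. It called 20 with no filter, where more genes were tested, 21 without trend, 126 with array weights and 173 with array weights on genes above 0 in every library, and 9 to 91 on leaving out single libraries. For mrpl1-1 the 7 calls became 4 with a pseudocount of 5, 4 with no filter, 2 with a filter of 5 FPKM, 18 with array weights, 2 on genes above 0 in every library, 21 with array weights on these and 4 on protein-coding genes of at least 300 nt, and 5 to 11 without single libraries. For the difference the 70 calls became 112 with robust moderation, 191 with array weights, 136 on genes above 0 in every library, 285 with array weights on these and 143 on protein-coding genes of at least 300 nt, and 17 to 197 without single libraries. The cause was not tested. The 8 lists called with doxycycline became 0 with an estimated correlation and 2 with fry, and 5 to 8 without single libraries; the 9 of mrpl1-1 became 0 and 0, 5 without both libraries that stood apart, and 4 to 13 without single libraries; the 12 of the difference became 0 and 4, and 10 to 12 without single libraries. The correlation of responses, 0.41, was 0.31 on genes above 0 in every library and 0.30 to 0.57 without single libraries. The respiratory chain list in the difference turned to the higher side with quantile normalization (adjusted p = 0.743), and the cause was not tested; no other called list and no called named gene changed direction in the fits run for it. Called lists of the 3 comparisons kept their calls in 367 of 459 fits, but each of the 29 lost its call at least with an estimated correlation; uncalled lists gained a call in 17 fits. Called named genes kept their calls in 295 of 384 fits, and 12 of the 30 calls were never lost. Those 12 include genes listed at 0 in every library of 1 group, among them ATCG00230, ATCG00410, AT1G74456 and AT1G20015. Uncalled named genes gained a call in 3 of 430 fits. These were 1 fit each for AOX1A, HSP23.5 and LRX1 with doxycycline (limma, lowest adjusted p = 0.00851, 0.0422 and 0.0368). MRPL1 stayed uncalled in 24 of 24 fits. Replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated between -0.0756 and 0.0817, and 3 of 9 libraries correlated best with their own number. With the replicate block the counts were 7 for doxycycline, 6 for mrpl1-1 and 42 for the difference. Simulations with 200 planted changes recovered 38.8% of 2-fold changes in mrpl1-1 against wild type, so changes of that size were often not detectable there. With only 7 calls the cutoff in the data was stricter, so the share detectable may be lower still.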

Other observations

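The lists in this part were made after seeing the data. The root hair genes leave out RHS13, already seen, but hold LRX1, COBL9 and EXP7 of the root markers, whose fall had been seen, so the list is not independent evidence. None of 16 measured root hair genes passed over all genes with doxycycline (limma; 15 were lower at an unadjusted p under 0.05), 12 fell when adjusted over the list alone, and the median was -1.04 (camera, adjusted p = 4.6e-19; adjusted p = 0.0202 with an estimated correlation). RHS19, a root hair peroxidase, was at 9.39 ± 1.29 against 25.5 ± 5.85 FPKM and PRP3, a cell wall protein, at 17.2 ± 3.21 against 49.5 ± 12.6 (SD, n = 3), neither called over all genes (limma, adjusted p = 0.0725 and 0.0773). RHD2, an NADPH oxidase of root hairs, was at 6.39 ± 1.41 against 6.63 ± 0.495 FPKM (SD, n = 3; adjusted p = 0.934). Without the 3 shared genes, 9 of 13 fell adjusted over the list alone and the median was -1.02 (camera, adjusted p = 7.0e-15; adjusted p = 0.0316 with an estimated correlation). In the libraries labelled mrpl1-1 the list had a median of 0.28 (camera, adjusted p = 9.4e-05; adjusted p = 0.225 with an estimated correlation). Doxycycline against mrpl1-1 gave a median of -1.36, with 9 of 16 lower over all genes (camera, adjusted p = 1.6e-23; adjusted p = 0.00493 with an estimated correlation).

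Families were matched by product name, which leaves some members out. Of 53 class III peroxidases 2 fell with doxycycline over all genes, and 11 fell and 2 rose adjusted over the list alone; the median was -0.19, with 15 on the higher side (camera, adjusted p = 1.4e-05; adjusted p = 0.0316 with an estimated correlation). Camera called as higher ABC transporters (median 0.14, 1 of 52 rose, adjusted p = 0.000853), MATE efflux proteins (0.16, 1 of 38, adjusted p = 0.00191), UDP-glycosyltransferases (0.08, 2 of 99, adjusted p = 0.0248) and pentatricopeptide repeat proteins (0.13, 0 of 256 by limma and 18 at an unadjusted p under 0.05, adjusted p = 0.000218). With an estimated correlation none of these was called (camera, adjusted p = 0.130, 0.354, 0.354 and 0.175). Histones were called as lower (-0.19, 0 of 28 by limma and 6 at an unadjusted p under 0.05, adjusted p = 0.000605, or 0.361 with an estimated correlation). The ABC transporters matched do not include ABCB4 (limma, adjusted p = 0.0128) and ABCA7 (adjusted p = 0.0271), which rose. Some families hold genes already called with doxycycline, such as AT2G04050 and UGT73B4, so their tests are not independent evidence. Whether the length trend of the doxycycline libraries shaped these shifts, or those against mrpl1-1 below, was not tested. Not called were cytochrome P450s (median -0.01, adjusted p = 0.901), WRKY factors (0.05, adjusted p = 0.342), mitochondrial carriers (0.02, adjusted p = 0.526), cytosolic-type ribosomal proteins (-0.000473, adjusted p = 0.765), extensins and related proteins (-0.03, adjusted p = 0.0846) and small nucleolar and spliceosomal RNAs (-0.50, adjusted p = 0.123).

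In the libraries labelled mrpl1-1 camera called as higher class III peroxidases (median 0.16, adjusted p = 0.00189), extensins and related proteins (0.14, adjusted p = 0.000838), WRKY factors (0.09, adjusted p = 0.00233) and cytosolic-type ribosomal proteins (0.09, adjusted p = 0.0443). No member of these 4 families passed over all genes (limma; 5 of 55, 16 of 191, 5 of 37 and 4 of 269 were higher at an unadjusted p under 0.05), and with an estimated correlation they had adjusted p = 0.640, 0.640, 0.225 and 0.694. The other 8 families were not called (adjusted p from 0.126 to 0.921). In doxycycline against mrpl1-1 the medians of the called families were -0.37 for peroxidases (adjusted p = 1.0e-08), -0.17 for extensins and related proteins (6.3e-06), 0.25 for ABC transporters (1.7e-05), 0.20 for MATE efflux proteins (0.00131), 0.17 for pentatricopeptide repeat proteins (1.7e-05) and -0.35 for histones (9.5e-05). With an estimated correlation none of these 6 was called (adjusted p = 0.134, 0.335, 0.160, 0.218, 0.0602 and 0.287).

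The rise of SEN1 in the libraries labelled mrpl1-1 raised the hypothesis of a carbon starvation or dark-induced programme. A list of such genes, made without those already seen, had a median of 0.232 over its 19 measured members (camera, adjusted p = 7.4e-05). None of the 19 passed over all genes (limma), and 4 rose when adjusted over the list alone. The median lay between the bounds of 0.1 and 0.3 set beforehand. The adjusted p was 0.115 with an estimated correlation (camera) and 0.0128 with fry, so such a programme may be present but was not settled.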
